A study of Mus musculus with 4 samples.

How the data were processed

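HTATSF1 ChIP-seq and input chromatin libraries were made from floxed, inducible-Cre mouse embryonic stem cells, with 2 libraries of each kind; per the labels' protocols, they were barcoded and sequenced as single-end reads. Samples were grouped by their titles, and the replicate numbers come from the same titles. Peak lists of the 2 immunoprecipitated libraries were used. Values of the input libraries were not analysed here.

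The authors deposited 1 peak list per immunoprecipitated library, not a list from pooled libraries, with a start, an end, a name and a score for each peak. Per the submitters' processing notes, the tools were Bowtie, Picard 1.82 and bedtools and the genome build was mm9; their settings, and the role of each, are not given in the sources used here. The peak names in the deposited files begin with MACS, the name of a peak caller, whose version, threshold and control are not given in the sources used here. What the deposited score measures is not stated in the files either: no value lies under 50 in either list. One reading is the negative logarithm of a p-value, scaled and cut at a limit, a significance value that depends on depth, but no source used here states it. Its sizes were compared within a list only. Between lists, scores entered as ranks, apart from 1 correlation of log scores. Scaling scores in the closing section is an assumption about what they measure. The deposited positions (other values of the files) were used as given and are printed counted from 1. A reference table of another build, GRCm38, was at hand for gene names; 161 replicate 1 peaks and 115 replicate 2 peaks lie past the last gene of their chromosome in it, so none of its coordinates were used. Only the number of its protein-coding genes on each chromosome entered, in the closing section. For the same reason the planned shares of peaks at promoters and in gene bodies, and the planned comparison of 17 gene lists (ribosomal proteins, ribosome assembly, splicing, pluripotency, feeder fibroblast markers and others), were not run, with each of their alternatives.

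Peaks were called shared when they overlapped a peak of the other list by at least 1 bp. Chance overlap came from 1000 circular shifts of the replicate 2 peaks within the span of the peaks on each chromosome. Scores of shared peaks were compared by Spearman correlation, each replicate 1 peak with its highest-scored partner, and median scores of shared and unshared peaks were compared within each list, both with 100000 permutations over peaks. Binomial intervals are exact (Clopper-Pearson) at 95%. The named regions are, by a rule fixed before the data were examined, the 15 shared peaks with the highest mean percentile rank of score over both lists; the 100 kb windows and the chromosomes singled out were chosen after their values were seen. The chance of windows dense in both lists came from 1000 rotations of the replicate 2 windows within each chromosome. The overlap and permutation code was tested on simulated lists with the real widths and chromosome spans, built from 19406 replicate 1 peaks: it recovered 98.7% of 5000 planted shared peaks, and independent lists gave 0.868 times the mean of their shifts.

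Alternatives fixed before the data were examined were the upper 50% of each list by score, an overlap of at least 50% of both peaks, random placement of each peak, autosomes only, and the opposite direction of counting. Added after the data were seen were a distance of 1 kb counted as shared, merging peaks under 1 kb apart, lists of equal length, shifts of 20 to 200 kb, and leaving out chromosome 8. Depth limits the lists in a way that cannot be measured from them. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.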

Results

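Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to find the chromatin regions that carry HTATSF1 in mouse embryonic stem cells. HTATSF1 (HIV Tat specific factor) is a nuclear protein with RNA recognition motifs that is known to associate with the splicing machinery. The cells carried a conditional (floxed) allele of the gene and an inducible Cre recombinase, were grown on fibroblast feeders, and were untreated. The series held 2 immunoprecipitated libraries, made with a rabbit antibody raised against a peptide of mouse HTATSF1, and 2 input libraries of chromatin taken without antibody. Each immunoprecipitated library had its own list of peaks in mm9 coordinates, with a score per peak from the authors' peak caller. These lists are the data compared here. The sequencing depth behind them is unknown, so no interval for reads can be given, and the input libraries entered no comparison. The labels do not say whether the libraries came from separate cultures, so differences between them may be technical.

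HTATSF1 peaks numbered 19489 in replicate 1 and 14118 in replicate 2, on chromosomes 1 to 19 and X in both. They were narrow. The median width was 402 bp in replicate 1 and 289 bp in replicate 2, and the peaks covered 8.85 Mb and 4.60 Mb of the genome. The lowest score was 50.01 in replicate 1 and 50.00 in replicate 2, the median scores were 88.3 and 72.4, and the highest were 742.2 and 546.7. Wider peaks had higher scores, with a Spearman correlation across peaks of 0.79 in replicate 1 and 0.73 in replicate 2. Neighbouring peaks often lay close together: 14.9% of the gaps between successive peaks in replicate 1 and 11.8% in replicate 2 were under 1 kb. Joining such peaks left 16589 and 12460 regions, of which 2471 and 1465 held more than one peak.

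The first comparison asked which HTATSF1 regions were found in both immunoprecipitations. In replicate 1, 8882 peaks (45.6%, exact 95% binomial interval 44.9 to 46.3%) overlapped a replicate 2 peak by at least 1 bp. In replicate 2, 9205 peaks (65.2%, interval 64.4 to 66.0%) overlapped a replicate 1 peak. The intervals cover counting error only. The midpoints of overlapping peaks were a median of 79.3 bp apart, and 8237 of the shared replicate 1 peaks had a single partner. Some neighbouring replicate 1 peaks had the same partner, so these are not all one-to-one matches. The bases in both lists came to 3.03 Mb, which was 29.0% of the 10.4 Mb covered by either. When the replicate 2 peaks were moved around each chromosome in 1000 circular shifts, 96.2 ± 13.4 (SD) replicate 1 peaks overlapped by chance and never more than 173. The observed number was 92.3-fold higher (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). This shift ignores the uneven density of peaks along chromosomes: with shifts of 20 to 200 kb, which keep it, 301.6 ± 18.6 (SD) peaks overlapped by chance and the ratio was 29.5. The ratio was 217-fold when an overlap had to cover 50% of both peaks, which 5931 replicate 1 peaks met. All of these shifts place peaks without regard to genes or to the state of the chromatin. The overlap therefore shows that peak positions recurred. It does not test whether the antibody was specific, since no input or other control list was compared.

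Regions with high scores were found in both libraries more often than those with low scores. Among the 100 highest-scored peaks, 99 of replicate 1 and 100 of replicate 2 overlapped a peak of the other list. Among the 1000 highest-scored, 916 and 974 did. Shared peaks had a median score of 122.1 (quartiles 80.6 and 184.9) in replicate 1, against 72.8 (58.5 and 100.02) for the 10607 unshared peaks, a difference of 49.3. In replicate 2 the medians were 84.4 (63.8 and 119.9) and 60.6 (54.1 and 73.2), a difference of 23.8 over 4913 unshared peaks. Both differences had p = 1e-05 in a two-sided permutation test over peaks, the smallest that 100000 permutations can give. Peaks of a list are not independent replicates, so these p-values describe the lists. Shared peaks were also wider, with medians of 506 against 339 bp in replicate 1 and 343 against 211 bp in replicate 2. With each list split by score into 10 equal parts, from the lowest part to the highest the shared percentage went from 20.1% to 87.6% in replicate 1 and from 37.5% to 96.4% in replicate 2.

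**Figure D1:**
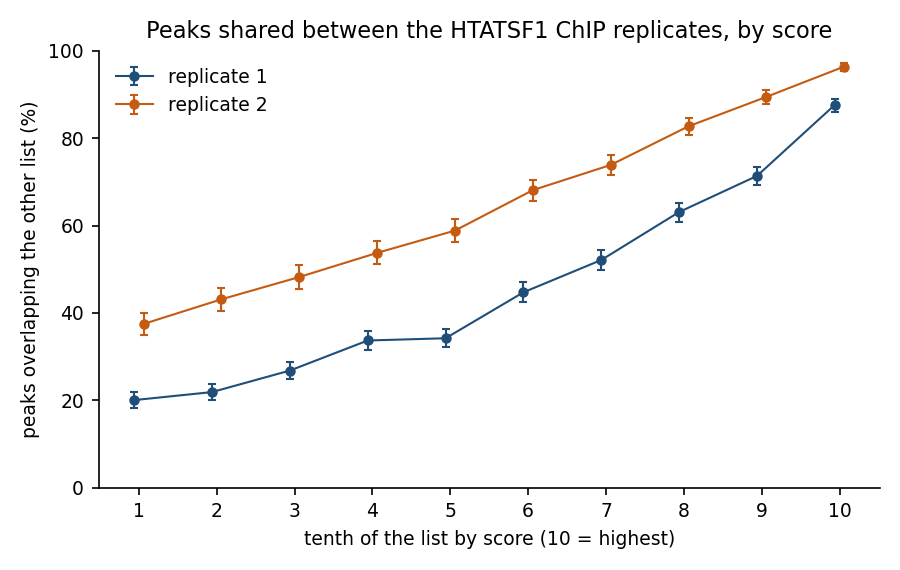
Percentage of peaks that overlap a peak of the other list (vertical axis) in each of 10 equal parts of a list ordered by score (horizontal axis, 10 highest), for the 2 HTATSF1 ChIP replicates; points are percentages and bars exact 95% binomial intervals. The percentage reaches 87.6% in replicate 1 and 96.4% in replicate 2 in the highest part.

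Within the shared regions the order of scores agreed in part. Across the 8882 shared replicate 1 peaks, each paired with its highest-scored partner, the Spearman correlation of scores was 0.37 (p = 1e-05, permutation test, the smallest possible) and the Pearson correlation of log scores 0.41. These correlations are across peaks, which are not replicates, and some replicate 2 peaks entered more than once as the partner of neighbouring replicate 1 peaks. Peaks that covered each other by at least 50% gave a Spearman correlation of 0.51. That requirement limits how far the widths of paired peaks can differ, and wider peaks had higher scores. The higher value may therefore come in part from the requirement. Of the 100 highest-scored peaks of replicate 1, 24 overlapped one of the 100 highest of replicate 2, where circular shifts gave a mean of 0.022. For the 1000 highest, 367 did, against 0.909 by chance.

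**Figure D2:**
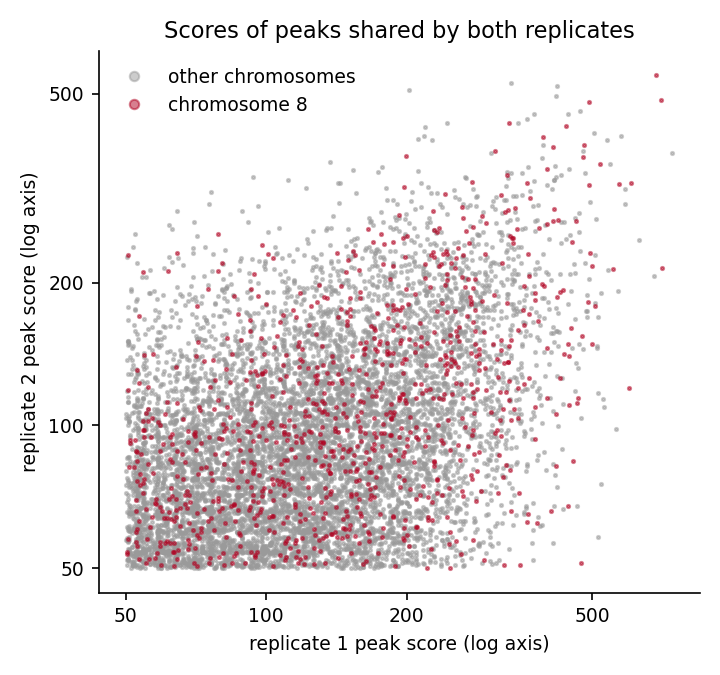
Peak score in replicate 1 (horizontal log axis) against the score of the highest-scored overlapping peak in replicate 2 (vertical log axis) for the 8882 shared replicate 1 peaks, 1 point per peak, with chromosome 8 in red. The scores follow each other loosely (Spearman correlation 0.37), and chromosome 8 peaks are frequent among the high scores of both lists.

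The 15 shared regions with the highest mean percentile of score over both lists had replicate 1 scores of 443.4 to 742.2 and replicate 2 scores of 324.5 to 546.7. Chromosome 8 held 7 of them, chromosome X held 2, and 6 lay on other chromosomes. The first was at chromosome 8, 23969520 to 23970375 (replicate 1 score 686.0), which overlapped the highest-scored peak of replicate 2 at 23969154 to 23970306 (score 546.7). The second, at chromosome 8, 112301814 to 112303063, scored 700.0 in replicate 1 and 486.2 in replicate 2. A pair of neighbouring peaks on chromosome X came next, at 166424222 to 166426058 (scores 576.7 and 407.4) and at 166426381 to 166429220 (scores 742.2 and 375.6), the latter being the highest score of replicate 1. They were the widest of the 15 in replicate 1, at 1837 and 2840 bp against a list median of 402 bp. Whether their signal reflects binding or an artefact of the region was not tested. The highest-ranked region outside chromosomes 8 and X was at chromosome 5, 149995453 to 149996500, with scores of 538.7 and 400.2. It was followed outside these chromosomes by chromosome 10, 79711543 to 79712460 (504.9 and 413.3), chromosome 14, 21166885 to 21167817 (544.2 and 356.0), chromosome 4, 108952539 to 108953147 (469.6 and 459.8), chromosome 11, 86570602 to 86571561 (476.6 and 378.9), and chromosome 3, 51287683 to 51288494 (443.4 and 454.4). The other 5 regions on chromosome 8 began at 124473586 (scores 490.9 and 481.2), 71317358 (519.5 and 355.8), 97855363 (479.9 and 389.3), 72497305 (603.5 and 324.5) and 13785236 (476.9 and 368.3). All positions are the replicate 1 peak in mm9, counted from 1. Genes, exons and introns at these positions are not given, because no annotation of mm9 was used here.

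HTATSF1 peaks were unevenly spread over the chromosomes, and the spread was alike in both lists. Chromosome 11 held the most, 1779 peaks (9.13%, exact 95% interval 8.73 to 9.54%) in replicate 1 and 1278 (9.05%, 8.58 to 9.54%) in replicate 2. Chromosome 8 came next with 1703 (8.74%, 8.35 to 9.14%) and 1276 (9.04%, 8.57 to 9.52%). The median over the 18 autosomes other than 8 was 907 peaks in replicate 1 and 649 in replicate 2. Per Mb between the first and last peak, chromosome 8 had 13.3 peaks in replicate 1 against a median of 7.84 for those autosomes, and 9.94 against 5.74 in replicate 2. Chromosome X had 85 peaks in replicate 1 and 80 in replicate 2, or 0.534 and 0.502 per Mb. The autosome with the lowest density, chromosome 3, had 5.01 and 3.69 per Mb.

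Chromosome 8 also had the highest scores of the 19 autosomes in both lists. Its median score was 97.9 in replicate 1, where the other autosomes ranged from 84.1 (chromosome 12) to 90.9 (chromosome 3). In replicate 2 it was 81.7, against a range from 67.7 (chromosome 18) to 74.8 (chromosome 17). The 90th percentile was 268.2 against at most 215.3 elsewhere on the autosomes in replicate 1, and 184.6 against at most 154.2 in replicate 2. Peaks on chromosome 8 were shared more often than on any other autosome: 54.0% (exact 95% interval 51.6 to 56.4%) against at most 46.6% in replicate 1, and 76.3% (73.8 to 78.6%) against at most 68.9% in replicate 2. Sharing rose with score in both lists, so this is not separate from the higher scores of chromosome 8. Sharing was not compared at equal scores. Chromosome 8 held 34 of the 100 highest-scored peaks of replicate 1 and 23 of those of replicate 2. Without chromosome 8, 7962 replicate 1 peaks (44.8%) were shared and the Spearman correlation of scores was 0.36. The intervals given here are for chromosome 8 alone. The closing section compares its median score with that of chromosome 11. Outside the densest windows it also compares it with the highest other autosome. There the median of chromosome 8 was 95.1 in replicate 1 and 78.8 in replicate 2. The highest other autosome had 95.4 (chromosome 18) and 77.3 (chromosome 17). No clear difference was left, but the highest other median was also higher there than over all peaks. The differences in this paragraph were otherwise not tested.

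**Figure D3:**
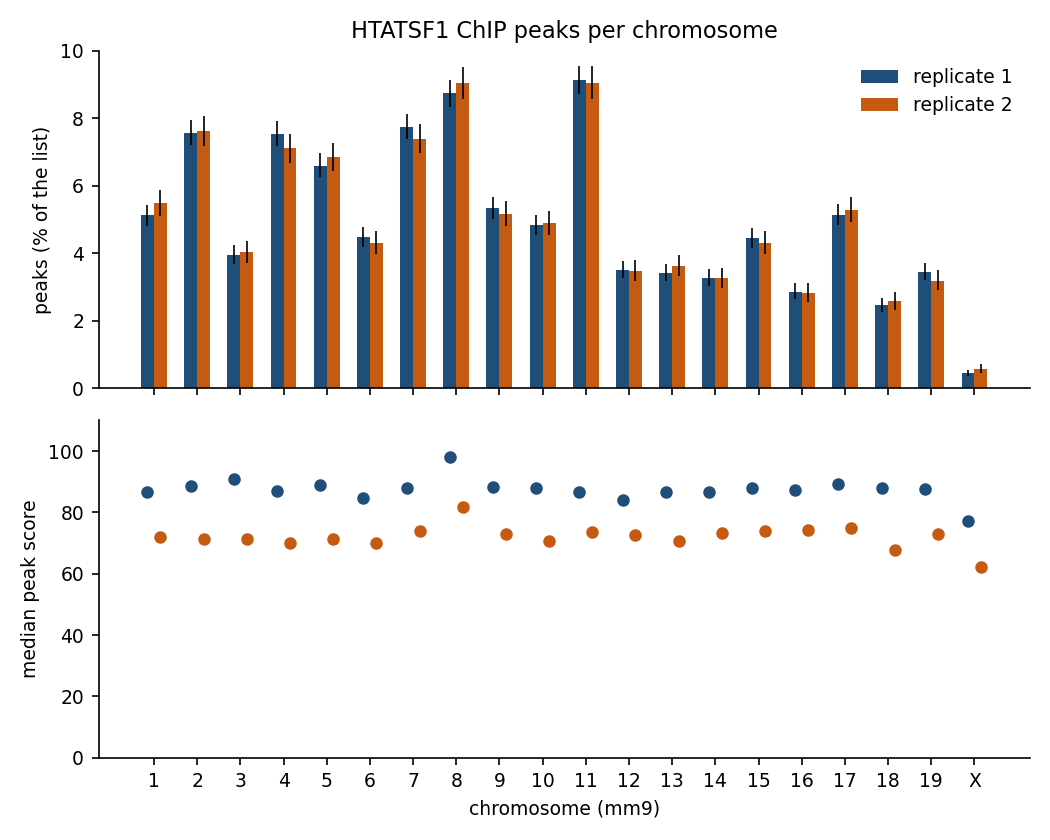
Percentage of each list's peaks (upper panel, bars from 0 with exact 95% binomial intervals) and median peak score (lower panel, 1 point per list) for each mm9 chromosome (horizontal axis), in the 2 HTATSF1 ChIP replicates. Chromosome 8 has the highest median score in both lists (97.9 and 81.7), and chromosome X has the fewest peaks (85 and 80).

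Windows of 100 kb that were dense in HTATSF1 peaks in replicate 2 were mostly dense in replicate 1 too. The median number of peaks per occupied window was 2 in replicate 1 and 1 in replicate 2. At least 10 peaks lay in 147 windows in replicate 1 and in 32 windows in replicate 2, and 26 windows met this in both lists, 12 of them on chromosome 8. When the windows of replicate 2 were rotated within each chromosome 1000 times, a mean of 0.467 and at most 6 windows were dense in both (one-sided permutation p = 0.001, the smallest possible). In the 26 windows, 62.1% of the 390 replicate 1 peaks and 80.7% of the 326 replicate 2 peaks were shared. Over all peaks the shares were 45.6% and 65.2%. The windows were chosen for many peaks in both lists, which by itself favours overlap, so the higher shares are not separate evidence about dense windows. The window with the highest mean count, at chromosome 8, 73100001 to 73200000, held 21 and 18 peaks, of which 15 and 18 were shared. The next, at chromosome 8, 123000001 to 123100000, held 25 and 13 peaks, of which 10 and 9 were shared. A pair of chromosome 8 windows tied for the place after it: 86700001 to 86800000 (21 and 15 peaks, 12 and 13 shared) and 87500001 to 87600000 (17 and 19 peaks, 14 and 17 shared). Outside chromosome 8 the densest was at chromosome 7, 28100001 to 28200000, with 17 and 11 peaks, of which 8 and 8 were shared.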

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

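Of 31 alternative values, 26 kept their direction and their side of the threshold or, for a count of shared peaks, stayed within 1.5 times the main count. The other 5 were 1 such count and 4 chromosome percentages outside the 95% binomial interval of the main percentage. None changed direction. The number of shared replicate 1 peaks fell to 4521 in the upper 50% of each list by score, where fewer peaks were compared, and lay between 5931 (overlap of at least 50% of both peaks) and 10564 (a replicate 2 peak within 1 kb) under the others. The ratio to chance lay between 29.5 (shifts of 20 to 200 kb) and 217 (overlap of at least 50% of both peaks), each with p = 0.001 by permutation. In the upper 50% of each list by score, the part on chromosome 8 was 9.80% in replicate 1 and 10.5% in replicate 2, and the part on chromosome X was 0.287% and 0.397%. These shifts restate the scores and are not a separate result. Median scores of chromosome 8 (97.9 and 81.7) lay above those of the lists (88.3 and 72.4). Those of chromosome X (77.2 and 62.3) lay below. The cause of these score differences was not settled. The settings added after the data were seen are the 1 kb distance, merging, equal lengths, the shifts of 20 to 200 kb and leaving out chromosome 8. Leaving out a replicate gives no value for the overlap, which needs both lists, and the counts per chromosome are given for each list alone. No paired analysis was possible because the input libraries that share replicate numbers with the immunoprecipitated ones were not analysed here. The planned promoter, gene body and gene list results, with their alternatives, were not run, since no mm9 annotation was used. The unknown depth limits how far an unshared peak can be read as an unbound region.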

Other observations

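The tests below were chosen after the results they bear on were seen, except that of the distance of unshared peaks. The criteria for the chromosome X count and for dense segments as the source of the number of peaks on chromosome 8 were also changed after their values were seen: under the first criteria both explanations were excluded, and under those used here both stay open. The criterion used here would exclude a single X copy only if X had as many peaks per gene as the lowest autosome. The values already seen did not meet that, so this test could not exclude a single copy. Peaks on chromosome X were few but included the highest score of replicate 1. The window at chromosome X, 166400001 to 166500000, held 15 of the 85 X peaks of replicate 1, of which 9 were shared, and 13 of the 80 of replicate 2, of which 10 were shared. Elsewhere on chromosome X, 14 of 70 and 14 of 67 peaks were shared, and scores reached at most 210.6 and 148.5. The highest-scored unshared peak of replicate 1 was at chromosome 18, 10609784 to 10610641, with a score of 426.4 and the nearest replicate 2 peak 6.94 kb away. In replicate 2 it was at chromosome 15, 36398805 to 36399393, with a score of 235.0 and the nearest replicate 1 peak 26.9 kb away.

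Chromosome 8 had more peaks per protein-coding gene (genes counted per chromosome in GRCm38) and higher scores than every other autosome in both lists: 1.63 peaks per gene in replicate 1, where the others had at most 1.11, and 1.22 against at most 0.794 in replicate 2. A greater density of sites per Mb is argued against as the only source of the higher scores. Chromosome 11, the only autosome with more peaks per Mb, had a median score lower by 11.2 (95% block bootstrap interval 4.97 to 19.7) in replicate 1 and by 7.92 (2.97 to 13.3) in replicate 2. This comparison rests on chromosome 11 alone, which had fewer peaks per gene than chromosome 8. It does not bear on the number of peaks. A few dense segments stay open. The peaks of the densest 20% of 5 Mb windows on each autosome were left out. Counts were still divided by all genes of the chromosome, since gene positions were not used. Chromosome 8 then had 0.778 peaks per gene against 0.592 on chromosome 11 in replicate 1 (interval of the difference -0.0864 to 0.471). In replicate 2 it had 0.616 against 0.415 on chromosome 11 (0.00619 to 0.407). Its median score in replicate 1 was 95.1, against 95.4 on chromosome 18, the highest other autosome (difference -0.27, -10.8 to 11.5). In replicate 2 it was 78.8, against 77.3 on chromosome 17, the highest other autosome there (difference 1.46, -4.82 to 9.71). Over all peaks the medians of chromosome 8 were 97.9 and 81.7. The median scores of 5 Mb windows of chromosome 8 with at least 20 peaks were also compared with the median of the other autosomes. That median was a single value per list, 87.62 in replicate 1 and 72.015 in replicate 2. It was exceeded in 14 of 20 windows in replicate 1 and 14 of 17 in replicate 2. Windows of other autosomes were not counted in this way, and windows with fewer peaks were left out. The window counts therefore cannot decide whether dense segments are the source of the higher scores. An extra copy of chromosome 8, a common change in cultured mouse stem cells, is a candidate explanation that these lists cannot decide: scores must be divided by 1.79 (1.15 to 2.42) in replicate 1 and 1.56 (1.19 to 1.95) in replicate 2 to give as many peaks per gene as the other autosomes, where the highest factor of another autosome was 1.21 (chromosome 15), inside the interval of chromosome 8, and 1.13 (chromosome 11), below it. Whether the score is proportional to copy number is unknown, and a significance value would also depend on depth; input coverage was not analysed here, and a greater binding of HTATSF1 to chromosome 8 was not tested.

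Chromosome X had fewer peaks per gene than every autosome in both lists. A single copy of chromosome X may contribute: if halving the copies halved the score, 360 peaks would be expected in replicate 1 and 164 in replicate 2 from the other autosomes without 8, above the 85 (exact 95% Poisson interval 67.9 to 105) and 80 (63.4 to 99.6) in the lists. The shortfall is thus larger than this model gives, but the model assumes a score proportional to copies, which a significance value need not be, and as many sites per gene as on autosomes, so it excludes nothing, and the number of X copies is not given in the labels.

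Of the 19489 replicate 1 peaks, 10607 had no replicate 2 partner. Neighbouring positions called in both lists are argued against as the whole cause, since 15.9% of these unshared peaks had a replicate 2 peak within 1 kb, though circular shifts gave a mean of 1.56% and at most 2.31%. Circular shifts ignore the uneven density of peaks along chromosomes, so these chance values may be too low. Signal near the threshold stays open: the shared percentage was 58.5 percentage points higher in the 20% of replicate 1 peaks with the highest scores (79.5%) than in the 20% with the lowest (21.0%), but this restates the relation of sharing to score, and higher-scored peaks were also wider, which makes an overlap easier. A difference in depth or in yield of the immunoprecipitation was not tested.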
